A study of Mus musculus with 4 samples.

How the data were processed

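RNA from 2 wild-type and 2 B-type lamin null mouse embryonic stem cell samples was extracted as total RNA with Trizol and made into Illumina TruSeq RNA libraries, per the labels' protocols. The authors deposited 1 table of raw read counts per Ensembl gene, with a column for each library and the gene positions. TopHat2 2.0.6, TopHat and HTSeq are named in the submitters' processing notes, with no roles. The genome build, the annotation and whether counting used strand are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies can be divided or dropped by counting, and such genes are uncertain. Gene ends on chromosome 1 reach 197054592 in the table and 195323493 in GENCODE release M21, so positions are those of the table, in its own build. GENCODE M21 was used by gene ID for symbols, biotypes, transcript lengths and GC content, which gave symbols to 32938 of 37991 genes.

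Total counts per library ranged from 12899964 to 16697970. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of 14.1 to 34.2), and all 4 were used. Libraries were grouped by the genotype in their titles. Log2 fold changes are dKO minus wt. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood F test with genotype as the only term, with Benjamini-Hochberg adjustment over 14027 genes and a threshold of 0.05. CPM values are scaled by TMM, and SEs were computed from the F statistic. Gene lists (30, fixed before the data were examined), chromosomes and gene-density classes with at least 4 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries, so calls over many lists are hard to reach. Gene density counted protein-coding genes within 500 kb of the gene start, and classes with at most 7 and at least 29 such genes were compared. The lists cover lamina and envelope, nucleoporins, naive and general pluripotency, epiblast, primitive endoderm, mesendoderm, neuroectoderm, trophoblast, germline, 2-cell, homeobox, imprinted, p53, mitosis, replication, interferon, actin and SRF, fibroblast, cholesterol, hypoxia and glycolysis, stress, heterochromatin, histone, mitochondrial, olfactory, protocadherin, Y-linked, X-inactivation and blood genes.

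Named genes were fixed by rule. Lmnb1, Lmnb2 and Lmna were always named, then up to 12 genes with the largest rise and 12 with the largest fall past the threshold, with average log2 CPM of at least 2, genotypes that did not overlap and no predicted-gene name. From each list up to 2 risen and 2 fallen members were taken, or else up to 2 members with the highest CPM. Some genes that the rule allows are not reported here.

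The scripts were tested on simulated counts with the means, dispersions and library sizes of the dKO and wt libraries over 14027 genes. Changed genes were drawn from those with a mean CPM of at least 1. The test recovered 6% of 50 genes changed 1.5-fold, 52% of 50 at 2-fold, 88% of 50 at 4-fold and 96% of 50 at 8-fold. Of the 138 calls 17 (12.3%) were false, above the nominal 0.05 share. The data gave 12 calls, so the adjusted threshold was stricter there and recovery may be lower than in the simulation. All 20 simulated sets of 20 genes shifted by 0.5 log2 units were called and 0 of 100 unchanged sets. Genes were simulated independently of each other, so this did not test how often sets of correlated genes are called falsely.

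Alternatives were DESeq2 size factors, total counts only, no filter, a CPM of at least 1 in all libraries of a group, a replicate block, each library left out, the DESeq2 1.42.0 Wald test on unfiltered genes, limma-voom, an adjusted p of 0.01, a glmTreat test against 1.5-fold and lists without genes of the Y chromosome. Removal of a GC content and length trend from the set statistics, and the same statistics with no trend removed, were added after the data were seen, as was the DESeq2 test on the filtered genes. Parents of pseudogenes were found with blastn 2.17.0 against protein-coding transcripts of GENCODE M21. With 2 replicates per genotype, exact permutation of a single value cannot go below p = 0.333.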

Results

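Gene expression was measured by RNA sequencing in mouse embryonic stem cells of 2 genotypes, wild type (wt) and null for both B-type lamins (dKO). Lamins are intermediate filament proteins that line the inner nuclear membrane. B-type lamins are encoded by Lmnb1 and Lmnb2, and A-type lamins by Lmna. Each genotype was represented by 2 biological replicates, and all 4 libraries carried the same strain label, ZHBTc4. Total counts were 12899964 and 14941952 in wt replicates 1 and 2, and 16697970 and 16584014 in dKO replicates 1 and 2. Across genes, Pearson's r of log2 CPM (counts scaled to library size) was 0.978 between the wt replicates and 0.981 between the dKO replicates. Between libraries of different genotype it was 0.984 for both replicates 1 and 0.982 for both replicates 2. It was 0.974 between wt replicate 1 and dKO replicate 2, and 0.966 between wt replicate 2 and dKO replicate 1. Same-numbered libraries of different genotype thus correlated more closely than replicates of 1 genotype, a pairing that the genotype-only model does not use. Genes are not independent replicates, and these coefficients describe the libraries only.

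The comparison of dKO with wt cells addressed whether transcript levels differ between embryonic stem cells with and without B-type lamins. Each genotype may be 1 line, so an effect of lamin loss cannot be told apart from a difference between lines. The targeted transcripts were nearly absent from both dKO libraries. Lmnb1 (ENSMUSG00000024590, chromosome 18, 56867467 to 56913078) had 607 ± 85.2 CPM in wt and 5.13 ± 1.26 CPM in dKO cells (SD, n = 2 each), a log2 fold change of -6.88 (SE 0.24, edgeR adjusted p = 0.00094). Its counts were 8538 and 8321 in the wt libraries and 69 and 101 in the dKO libraries. Lmnb2 (ENSMUSG00000062075, chromosome 10, 80363948 to 80380990) had 111 ± 8.83 CPM in wt and 2.90 ± 0.54 CPM in dKO cells (SD, n = 2 each), a log2 fold change of -5.26 (SE 0.19, edgeR adjusted p = 0.00094). Lmna (chromosome 3, 88285070 to 88313878) had 38.3 ± 8.57 CPM in wt and 32.4 ± 4.51 CPM in dKO cells (SD, n = 2 each). Its log2 fold change was -0.24, with a 95% interval of -0.75 to 0.27 (edgeR adjusted p = 0.978).

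Apart from the targeted genes, 4 protein-coding genes and 6 pseudogenes passed the test. Nod1 (chromosome 6, 54873936 to 54922606), an intracellular sensor of bacterial peptidoglycan, rose from 2.72 ± 0.13 to 38.9 ± 12.04 CPM (log2 fold change 3.83, SE 0.29). Epas1 (chromosome 17, 87153247 to 87232750), a hypoxia-inducible transcription factor, rose from 14.5 ± 2.32 to 53.3 ± 0.70 CPM (1.88, SE 0.17). Tex15 (chromosome 8, 34627210 to 34696054), a gene of male germ cells, fell from 64.2 ± 4.61 to 19.6 ± 1.98 CPM (-1.71, SE 0.15). Eif2s3y (chromosome Y, 346986 to 365290), which encodes a subunit of a translation initiation factor, fell from 85.2 ± 3.54 to 26.9 ± 0.03 CPM (-1.66, SE 0.13). The edgeR adjusted p was 0.0288 for Nod1 and Eif2s3y, 0.0452 for Tex15 and 0.0471 for Epas1.

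The pseudogenes were almost present or absent by genotype. Pcna-ps2 on chromosome 19 had 1 count in each wt library and 638 and 700 in the dKO libraries, a ratio of 567 with a 95% counting interval of 157 to 4685. Tdg-ps on chromosome 15 had 214 and 177 counts in wt and 1 and 0 in dKO libraries, a ratio of 461 (82.3 to 18274). The other 4 have predicted-gene names and were named after their values were seen. Gm13456 rose from 1.18 ± 0.09 to 82.2 ± 11.4 CPM, and Gm10499 fell from 23.0 ± 8.25 to 0.45 ± 0.03 CPM. Gm11868 had 0 and 1 counts in wt and 132 and 114 in dKO libraries, a ratio of 208 (37.1 to 8265). Gm9855 had 199 and 193 counts in wt and 0 in both dKO libraries, at least 154-fold lower against a floor of 3 counts over the group. Such copies share sequence with their parent genes, so their counts are uncertain, and intervals and floors cover counting error only.

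**Figure D1:**
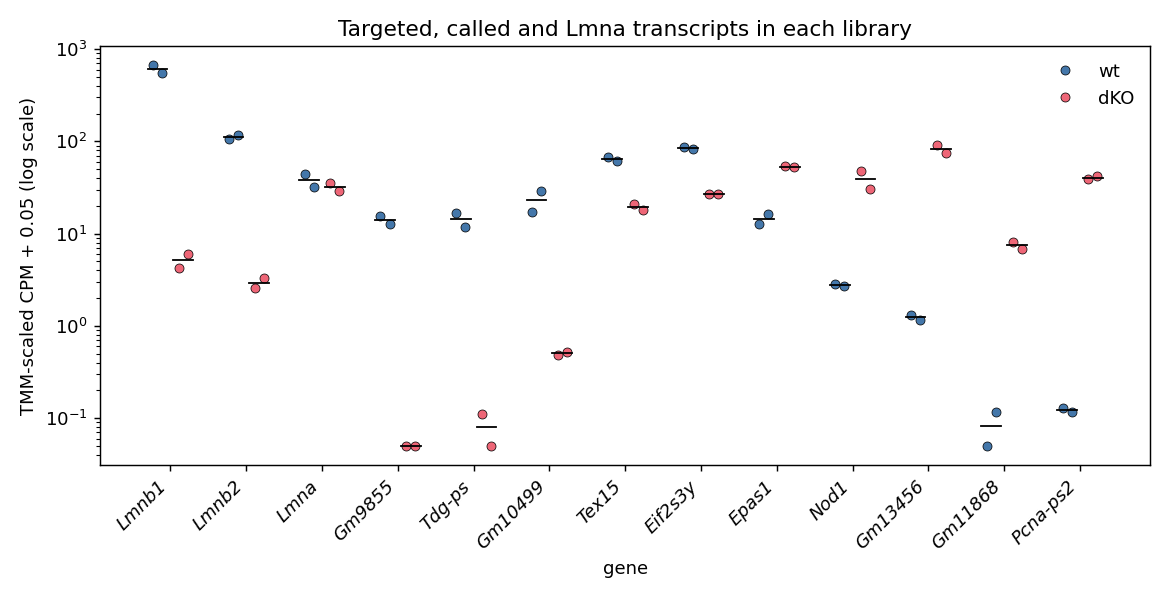
TMM-scaled CPM plus 0.05 on a log axis for Lmnb1, Lmnb2, Lmna and the other genes past the threshold, with 1 point per library (blue, wt; red, dKO) and a line at each group's mean. Lmnb1 lies at 607 CPM in wt and 5.13 CPM in dKO cells on average, while the Lmna points of the genotypes overlap.

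In all, 12 of 14027 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 5 higher and 7 lower in dKO cells, each by at least 2-fold. At an unadjusted p under 0.05 there were 782 genes. The median absolute log2 fold change was 0.164, and the 95% interval lay within 1 of 0 for 9182 genes (65.5%). The count of called genes depended on the method, and was highest by far with a replicate block, as given below. The count was 6 by limma-voom, 80 in edgeR with no low-count filter, 92 by DESeq2 with no filter and 96 by DESeq2 on the same 14027 genes, the last chosen after the data were seen; limma-voom did not call Nod1, Epas1, Tex15, Tdg-ps, Gm10499 or Gm11868 (adjusted p 0.0705 to 0.134), and without TMM scaling Epas1 (0.0724) and Gm11868 (0.0637) were not called. It was 19 without wt replicate 1 and 27 without wt replicate 2, with all 12 genes among them.

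With a preset correlation, genes of the naive pluripotent state were called higher as a group in dKO cells. Genes of the 2-cell-like state, a rare state of these cultures, were called lower. Neither list was called with an estimated correlation, a setting limited by the few libraries. Of the 17 naive pluripotency factors 11 had positive and 6 negative log2 fold changes, with a median of 0.26 (camera adjusted p = 9.5e-06; adjusted p = 0.519 with an estimated correlation). No member passed over all genes in edgeR, 4 had an unadjusted p under 0.05, and 4 passed when adjusted over the list alone. Zfp42 had 640 ± 36.9 CPM in wt and 1442 ± 10.1 in dKO cells (1.17, adjusted p = 0.0886 in edgeR), and Esrrb had a log2 fold change of 0.32. The median was 0.17 without wt replicate 1 and 0.41 without wt replicate 2, and the list stayed called. Fgf4 (0.76), Nr0b1 (0.62), Klf4 (0.57) and Nanog (-0.04) were chosen after their values were seen. All 8 measured 2-cell genes had negative values, with a median of -1.42 (camera adjusted p = 4.9e-09; adjusted p = 0.519 with an estimated correlation). None passed over all genes in edgeR, 4 had an unadjusted p under 0.05, and 3 passed when adjusted over the list alone. Tmem92 had a log2 fold change of -2.17 and Zfp352 of -0.20; Zscan4c (-2.21) and Zscan4d (-2.15), chosen after their values were seen, are near-identical copies whose counts are uncertain. All of these were low, with Tmem92 at 3.57 ± 0.03 CPM in wt cells (SD, n = 2).

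General pluripotency genes were not called. Pou5f1 had 813 ± 88.4 CPM in wt and 806 ± 22.4 CPM in dKO cells (SD, n = 2 each), a log2 fold change of -0.01 (SE 0.13), and L1td1 had 0.14. The test for this list pointed up and its median was -0.01. Post-implantation epiblast genes (median -0.06, with Dnmt3b at -0.35) were not called, and there too the test pointed up. Primitive endoderm (0.02, with Apoe at 0.35), mesendoderm (-0.16, with Nodal at -0.16), neuroectoderm (0.08, with Stmn2 at 0.34), trophoblast (-0.24, with Krt8 at -0.65) and germline genes (0.22, with Tdrd12 at -0.10) were not called either. Several of these medians moved when 1 library was left out, without a call: epiblast to 0.13 and neuroectoderm to 0.43 without wt replicate 1, primitive endoderm to 0.18 without wt replicate 2 and -0.13 without dKO replicate 2, mesendoderm to -0.32 without dKO replicate 1, and germline to 0.11 without dKO replicate 2. The trophoblast median was 0.34 without wt replicate 2, 0.08 without dKO replicate 1 and -0.78 without dKO replicate 2, where the list was called lower (adjusted p = 0.00053). Germline genes were called with no low-count filter (adjusted p = 0.0478). Markers of other cells that cultures can hold were not called: fibroblast markers had a median of -0.11 (Fn1 0.24, Vim -0.12), and blood and immune markers 0.04 (Laptm5 0.60). The fibroblast list was called lower without wt replicate 1 (median -0.34, adjusted p = 0.0482) and had a median of -0.57 without dKO replicate 2, and the blood list ran from -0.78 without dKO replicate 2 to 0.40 without dKO replicate 1.

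Other proteins of the nuclear envelope did not pass the test. The 18 measured lamina and envelope genes had a median of 0.07, with Tmpo at 0.08 and Psip1 at 0.07; their mean was -0.01. The 25 nucleoporin genes had a median of 0.05, with Tpr at 0.14. Heterochromatin factors (0.08, Trim28 -0.01), replication genes (0.04, Mcm7 -0.09), mitosis genes (0.07, Top2a 0.14), p53 targets (-0.10, Ccng1 -0.14), cholesterol genes (-0.06), imprinted genes (0.18, Peg10 0.04) and homeobox cluster genes (0.25) were not called. Histone genes were not called and had a median of 0.04 and a negative mean of -0.19; 1 member passed when adjusted over the list alone. Several of these lists were called when 1 library was left out: histone genes (median -1.40, adjusted p = 3.8e-06) and p53 targets (-0.31, 3.4e-06) without wt replicate 2, imprinted genes without wt replicate 1 (0.15, 0.0133), homeobox genes without dKO replicate 1 (0.98, 0.0033), and nucleoporin (0.13, 0.032) and mitosis genes (0.11, 0.0206) without dKO replicate 2. The same medians had the opposite sign without another library: histone genes 0.24 and p53 targets 0.07 without wt replicate 1, imprinted genes -0.04 without wt replicate 2, homeobox genes -0.64 without dKO replicate 2, and nucleoporin genes -0.03 without dKO replicate 1. The mitosis median was 0.01 without dKO replicate 1. Other medians moved without a call. The replication median was 0.12 without wt replicate 2 and -0.003 without dKO replicate 2, and the heterochromatin median -0.02 without wt replicate 2. Cholesterol genes had -0.15 without wt replicate 1 and 0.09 without dKO replicate 2, and lamina and envelope genes 0.01 without dKO replicate 1. With no low-count filter, histone genes (-0.75, adjusted p = 0.0064) and mitosis genes (0.08, 0.0371) were called. Protocadherins (2 measured, Pcdhgc4 0.08) and X-inactivation transcripts (3 measured, Xist 0.58, 1 when adjusted over the list alone) were too few to test.

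Of the 28 lists tested, 9 were called, and 0 were called with an estimated correlation, where 0 also had an unadjusted p under 0.05. The few libraries limit the degrees of freedom of that setting, so a lost call need not mean that members were correlated. The stress list had an estimated correlation of -0.006, under the preset 0.01. Its unadjusted camera p still went from 0.00056 to 0.062. Stress response genes rose (median 0.23, adjusted p = 0.0039; adjusted p = 0.519 with an estimated correlation), with Hspa5 at 0.35 and Asns at -0.11. Of 1179 olfactory and vomeronasal receptor genes with a row, only 5 passed the filter, all under 5 CPM. These 5 were called higher (median 0.75, adjusted p = 0.0254, and 0.519 with an estimated correlation), led by Olfr985 at 1.05. Hypoxia and glycolysis genes fell (-0.19, adjusted p = 0.0076; adjusted p = 0.548 with an estimated correlation), with Pkm at -0.29 and Slc2a3 at 0.02. Mitochondrially encoded transcripts were called lower (median -0.11, adjusted p = 0.0364, and 0.747 with an estimated correlation), although mt-Co1 had 0.06 and mt-Co3 0.01. Their summed CPM overlapped between genotypes, at 32689 and 37378 in wt and 31534 and 38028 in dKO libraries. Actin and SRF target genes were called lower (median -0.23, adjusted p = 0.0398, and 0.548 with an estimated correlation), with Actb at 0.02 and Flna at 0.13. Their summed CPM hardly differed, at 5172 and 5147 in wt and 5122 and 5147 in dKO libraries. Interferon-stimulated genes fell (-0.23, adjusted p = 0.0466; adjusted p = 0.519 with an estimated correlation), with Bst2 at -0.73. No member of these 6 lists passed in edgeR over all genes or when adjusted over the list alone; at an unadjusted p under 0.05 there were 7 actin and SRF genes, 2 stress genes, 2 hypoxia genes and 1 in each of the others. With no low-count filter the olfactory median was -0.18 and the list was not called (camera adjusted p = 0.833). With a stricter filter the actin (adjusted p = 0.0511) and mitochondrial lists (0.102) were not called, and the olfactory list had too few members to test. Each of these 6 lost its call when 1 library was left out. The median stayed near its size for stress response without dKO replicate 2 (0.21, adjusted p = 0.061), olfactory receptors without wt replicate 2 (0.67, 0.0532) and hypoxia without wt replicate 1 (-0.15, 0.0862), and was larger in size for interferon without wt replicate 1 (-0.40, 0.0862). It shrank for hypoxia without dKO replicate 2 (-0.05, 0.514), and for mitochondrial (-0.02, 0.666; -0.05, 0.145) and actin genes (-0.06, 0.264; -0.04, 0.605) without wt replicate 2 and without dKO replicate 1. The interferon call was also lost with total counts only (-0.25, adjusted p = 0.056).

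**Figure D2:**
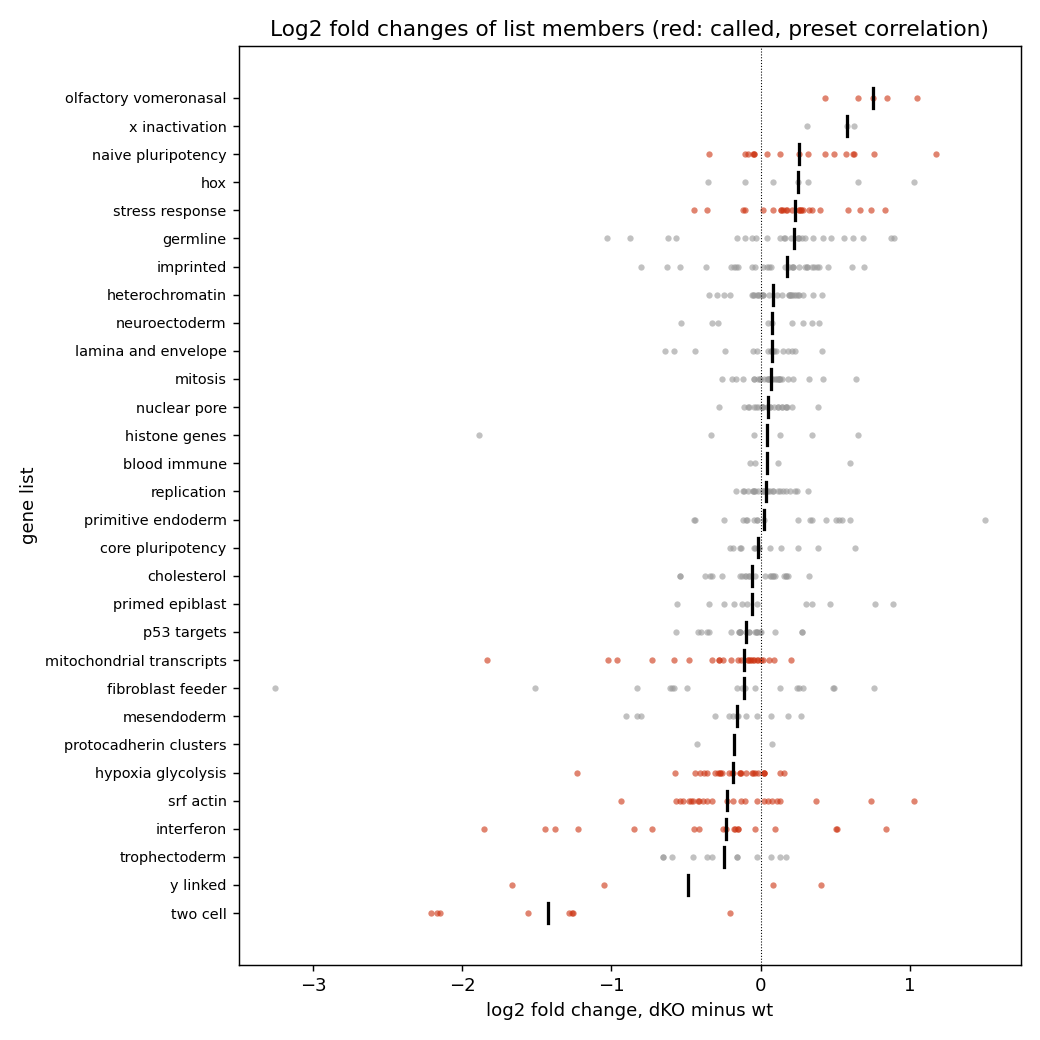
Log2 fold change (dKO minus wt, x axis) of each measured member of the 30 gene lists (y axis), with a black line at the list's median and red points for the 9 lists called with a preset correlation. The 2-cell list lies lowest with a median of -1.42, and 0 lists were called with an estimated correlation.

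Y-linked genes did not move together. Eif2s3y fell as given above, while Ddx3y had 70.4 ± 3.11 CPM in wt and 74.6 ± 4.13 CPM in dKO cells (0.08), Uty had a log2 fold change of 0.40 and Zfy1 of -1.05. As a list the 4 Y-linked genes were called lower (median -0.48, camera adjusted p = 0.0039; adjusted p = 0.519 with an estimated correlation), with 1 gene past the threshold over all genes and 2 adjusted over the list alone; without wt replicate 2 the median was -0.19. Among chromosomes, Y alone was called (5 genes, median -0.70, adjusted p = 0.0022; adjusted p = 0.485 with an estimated correlation), and that call was lost without wt replicate 1, wt replicate 2 or dKO replicate 1. The medians of the autosomes and X lay between -0.05 (chromosome 7) and 0.06 (chromosome 13).

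Regions at the lamina are gene-poor, and fold changes were therefore compared by gene density. Genes in gene-rich regions, with at least 29 protein-coding genes within 500 kb of their start, were slightly lower in dKO cells (2895 genes, median log2 fold change -0.06, camera adjusted p = 0.012; adjusted p = 0.0155 with an estimated correlation). Genes in gene-poor regions, with at most 7, had a median of 0.04 (2927 genes, adjusted p = 0.0638; adjusted p = 0.0155 with an estimated correlation). Median transcript GC content was 55.0% in gene-rich and 45.6% in gene-poor regions, and after a smooth trend on GC content and length was removed, chosen after the data were seen, the gene-rich median was 0.01 (adjusted p = 0.695). The gene-rich call was also lost without wt replicate 1 (adjusted p = 0.106) and without dKO replicate 2 (0.0824).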

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

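The DESeq2 test on filtered genes, the tests with a GC content and length trend removed, and those on the same z statistics without it, were chosen after the data were seen. Of 144 results, none reversed its test's direction with a call under the alternatives run. The count of 12 changed genes was 80 with no low-count filter, 92 by DESeq2 with no filter and 96 on the same 14027 genes, 6 by limma-voom, 4 at an adjusted p of 0.01 and 18 to 27 with 1 library left out. For changes of at least 2-fold it was 64 with no filter, 66 and 65 by DESeq2 without and with the filter, 6 by limma-voom and 18 to 27 with 1 library left out. DESeq2 gave a p but no adjusted p to 8534 of 22807 genes in its run with no filter and to 272 of 14027 in the other. Those genes could not be called. Lmnb1 and Lmnb2 kept their calls under every alternative run. With a replicate block, 1299 genes were called (641 up, 658 down, including the 12) and 288 at least 2-fold; same-numbered libraries deviated together across genes (r = 0.65), as a hint from the data and not the design. The block also moved the gene-poor median to 0.0467 (adjusted p = 0.0487), now called; it ended the calls of the mitochondrial (0.0572) and olfactory lists (0.0813), called the trophoblast (0.0152) and germline lists (0.0373), and changed no other list call. Called lists went from 9 to 5 with the stricter filter, where the olfactory and Y-linked lists had too few members to test. With an estimated correlation 0 lists were called, a setting in which the few libraries limit the degrees of freedom. The olfactory list had a median of -0.18 with no filter and was not called (camera adjusted p = 0.833). The Y chromosome's call became 0 calls with no filter, with an estimated correlation, with the trend removed and on z statistics without it, and 0 to 1 with 1 library left out. As the Y call was lost on z statistics alone, the trend was not needed to end it. The same held for the Y-linked and interferon lists (adjusted p = 0.233 and 0.0529 on z statistics), whereas the actin list was called on z statistics (0.0246) and not with the trend removed (0.0858), with medians of -0.23 and -0.19. The gene-poor class was also called with no filter (median 0.0514, camera adjusted p = 0.0248) and with an estimated correlation (median 0.0447, adjusted p = 0.0155). On z statistics it was called too (median 0.0444, adjusted p = 0.0423). The gene-rich median was 0.0113 with the trend removed, where its call ended, -0.06 on z statistics, where it held, and -0.0679 to -0.0512 with 1 library left out. For the other changes the cause was not tested. DESeq2 size factors and total counts moved the median of all genes by -0.0026 and -0.017. With these libraries and the genotype-only model, 52% of simulated 2-fold changes were recovered among genes with a mean CPM of at least 1. The simulation gave more calls than the data, so recovery in the data may be lower. Depth and replicate number were not varied.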

Other observations

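The test of distance from the targeted loci was chosen only after the result was seen, as was the GC-trend set test; the rules for the other tests were written before their results, and the counting interval on the 2-cell value, and its sum over members below the filter, were added after a first value was seen. Beyond the genes past the threshold, 3 further pseudogenes had absolute log2 fold changes of at least 3 and were named after their values were seen. Gm15920 on chromosome 5 had 32 and 28 counts in wt and 0 in both dKO libraries, and Gm13092 on chromosome 4 had 36 and 37 against 0. Gm6767 on chromosome 16 had 15 and 9 counts in wt and 129 and 115 in dKO libraries. Their edgeR adjusted p was 0.244, 0.205 and 0.217.

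Pseudogenes were near absent in 1 genotype in both directions. By the distance rule, 6 of the 6 called pseudogenes lay on other chromosomes than Lmnb1 and Lmnb2 or over 20 Mb away. A donor segment linked to the targeted loci is argued against for those on other chromosomes. Gm9855 lay on chromosome 10, as does Lmnb2, 38.6 Mb away. For it the cutoff, chosen after the result was seen, cannot exclude a longer segment. Sequence differences between the cell lines outside the targeted loci predicted more large changes among pseudogenes than among protein-coding genes. Leaving out called genes, 3 of 244 pseudogenes (1.23%) but 19 of 13016 protein-coding genes (0.146%) had absolute log2 fold changes of at least 3 (two-sided Fisher's exact test, p = 0.00732). Between the wt and between the dKO replicates 0 and 1 pseudogenes differed by that much. The classes were not matched for expression, and reads moved from parent genes could give the same excess, so this explanation stays open. All 4 libraries carried the same strain label. Whether reads moved between pseudogene and parent gene stays open, as the parent changed the opposite way by enough in 3 of 6 pairs. Among these, Tdg was the parent of both Tdg-ps and Gm9855, with a CPM change of 36.2 (95% interval 10.5 to 72.2, edgeR adjusted p = 0.674). The low end of that interval was smaller in size than the changes of Tdg-ps (-14.2 CPM) and Gm9855 (-14.1 CPM). Eef1a1, parent of Gm13456, had an interval that spans 0 (-714 CPM, -2560 to 1922). Cyb5r4, parent of Gm11868, changed the opposite way by less than the pseudogene's 7.42 CPM (-6.30 CPM, -16.5 to 6.66). Pcna and H2-D1 had differences of 17.2 and -1.57 CPM, in the direction of Pcna-ps2 and Gm10499 and with intervals that span 0. H2-D1 is a weak match, aligned with Gm10499 over 548 of 1698 bases at 92.9% identity. Lamin loss itself also stays open and was not tested apart from the lines' origin, since each genotype may be 1 line.

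Transcripts of the 2-cell list were lower in dKO cells. Reads shifted between near-identical copies within the list are argued against. The summed CPM of all 15 members with a row, 7 of them below the filter, was 26.3 and 15.7 in the wt libraries. It was 8.47 and 6.98 in the dKO libraries, a difference of means of 13.3 against SDs of 7.46 and 1.06. All 8 tested members were lower, so only those below the filter could have offset them. Their sum was lower too, at 5.32 and 2.76 CPM in wt and 2.03 and 1.07 CPM in dKO libraries. Copies outside the list were not summed, so reads shifted to those copies or dropped in counting stay open. Variation between replicate cultures of a jointly fluctuating group cannot be told apart from an effect of genotype: the wt replicates differed by 0.74 on the log2 scale (95% counting interval 0.50 to 0.98), against 1.40 between genotypes. With 2 libraries each, the exact permutation p of the sum was 0.333, the smallest the design allows. An effect of lamin loss remains a hypothesis.

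Log2 fold changes were lower in gene-rich than in gene-poor regions by a difference of medians of -0.10 (95% interval -0.12 to -0.08 over resampled chromosomes). Variation between libraries of 1 genotype is argued against for this difference, as it was at most -0.0078 in size between replicates. With 2 replicates per genotype that rests on few values. A GC content and transcript length trend may account for it, since -0.0097 was left after that trend was removed (95% interval -0.03 to 0.01). GC content and gene density go together along chromosomes. Spearman's rho of GC content with fold change was -0.19 across all genes, -0.16 within gene-rich and -0.05 within gene-poor genes. With the difference between replicates of 1 genotype it was 0.03 in wt and 0.09 in dKO, so some GC trend also lay between libraries of 1 genotype. Whether the GC trend arose in library preparation or in the cells was not tested.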
